A study of Mus musculus with 11 samples.

How the data were processed

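Bulk messenger RNA of whole mouse pancreas (strain C57BL/6JRj) was sequenced in 11 libraries, 1 per mouse by the labels. The mice were 7 weeks old (called young here) or 18 months old (called aged), and were either untreated or given caerulein, an analogue of the hormone cholecystokinin that makes acinar cells secrete and, in excess, injures them. There were 3 young untreated, 2 aged untreated, 3 young caerulein and 3 aged caerulein libraries. The labels number the aged untreated mice 2 and 3, and no library of a mouse 1 is in that group. Caerulein was given by intraperitoneal injection at 125 µg/kg, 4 times at hourly intervals, and the treated libraries are labelled 5H. The notes on timing can be read in more than 1 way, since the design text places sampling an hour after the first injection, so the time from the first injection is printed here only as that label.

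The authors captured polyadenylated RNA, sequenced 150-base read pairs, aligned them to the mm10 genome with HISAT2 2.0.5 and counted reads per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The strand setting, the annotation release, the read filters and the tool behind the authors' comparisons are not given in the sources used here. The deposited count table holds unnormalised whole-number read counts for 54532 genes. The deposited comparison tables hold the authors' log2 fold changes, and adjusted p-values stand beside them per the file headers. A deposited table of FPKM values was not used. Reads shared between close paralogs (amylases, trypsins, elastases, Reg3 genes, Hspa1a and Hspa1b, globins, immunoglobulins) and reads of overlapping genes on opposite strands are assigned as the authors' counting left them.

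Every fold change, level and p printed here was computed from the deposited counts, except where the authors' tables are named. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 14113. Libraries were scaled by TMM, and 1 model with 4 groups over all 11 libraries was fitted in edgeR 4.0.16 under R 4.3.3. Quasi-likelihood F tests were made for 5 comparisons, which were caerulein against untreated at each age, aged against young in each treatment, and the difference between the 2 caerulein responses. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Levels are TMM-scaled CPM (each count over its scaled library total, times 1e+06), given as mean ± SD over the libraries of a group, and log2 fold changes are given ± SE. Levels summed over a gene list or over immunoglobulin genes are CPM of unscaled library totals instead. A fold against a group with no counts was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact 95% counting interval. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Positions are those of whole genes on mm10.

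In addition, 40 gene lists written from general knowledge were tested with camera (limma 3.58.1) on log2 CPM, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. Of 1018 list symbols, 1017 were found. For each list the members that rose, fell or did not pass the edgeR test are counted over all genes tested, and again adjusted over the list alone. With a correlation estimated from the residuals in place of the preset value, 0 of the 40 lists passed in any of the 5 comparisons, and the adjusted p of that version is printed beside each list call. The rotation test fry asks whether a list moves at all, without comparing it with other genes.

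The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison, the 6 called genes with the largest change in each direction that have a mean of at least 5 CPM in the higher group and non-overlapping libraries (predicted genes, pseudogenes and immunoglobulin or T cell receptor segments left out). It also takes up to 4 members with the smallest p of each list described, and 29 fixed genes whether called or not. The alternatives were a stricter filter, no filter, a 2-fold minimum, DESeq2 size factors, library totals alone, DESeq2 1.42.0 in place of edgeR, abundant genes left out, only the groups compared, the mouse number as a block, a lymphoid score as covariate, an estimated correlation, fry, and each library left out in turn. Each comparison was also run without the library of young untreated mouse 2 (13567 genes tested) wherever a count is printed, an emphasis chosen after that library was seen to stand apart, and 2 pairs of choices with that library left out were added after seeing the data.

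Total counts ranged from 14223190 to 26537091 per library, and TMM factors from 0.696 to 1.29. The method was tested on simulated data with known changes added to genes of libraries of the same sizes. The spread of each gene was estimated over all 11 libraries, young untreated mouse 2 among them, and given to every library alike. The shares recovered therefore do not describe the comparisons made without that library. At 4-fold, between 42.4% and 68.2% of the changed genes were recovered, depending on the comparison. At 2-fold the share was 5.97% to 29.9%, and between 2 and 6 of 13886 unchanged genes were called by edgeR. DESeq2 called between 18 and 30 of the same unchanged genes, so its calls given below carry more false ones. These simulations changed few genes at a time, and in them most changes of 2-fold or less went uncalled.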

Results

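Gene-level read counts of pancreas were compared between young and aged mice, untreated or given caerulein, with 3 young untreated, 2 aged untreated, 3 young caerulein and 3 aged caerulein libraries. The study's stated purpose was the effect of aging at the start of pancreatitis. Total counts per library ranged from 14223190 to 26537091. Transcripts of digestive enzymes and zymogen granule proteins made up 74.7% ± 2.91 (SD, n = 3) of the counts in young untreated, 77.0% ± 1.67 (n = 2) in aged untreated, 59.1% ± 1.05 (n = 3) in young caerulein and 58.2% ± 2.17 (n = 3) in aged caerulein libraries. The share was lower after caerulein at both ages in every library (2-sided exact permutation p = 0.1 at each age, the smallest p these group sizes allow), while the groups of the 2 ages overlapped in untreated mice (exact permutation p = 0.6) and in treated mice (exact permutation p = 0.5). The first principal component of log2 CPM held 61.7% of the variance and parted treated from untreated libraries. The second held 14.5%, with young untreated mouse 2 at -107 and the other libraries between -8.45 and 29.3. The third held 6.52% and parted young from aged libraries in each treatment.

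The library of young untreated mouse 2 held transcripts of B cells, T cells, lymph node and fat far above the other 10. Summed over the B cell and plasma cell list it had 1360 CPM (of library totals), against 140 CPM in the next highest library, and over the T cell and NK cell list 315 CPM against 58.6 CPM. Lymph node stroma and follicle markers reached 141 CPM against 19.8 CPM, and adipocyte markers 2160 CPM against 289 CPM. Every comparison below that uses the young untreated group holds this library. Values without it stand beside many of the gene groups that moved with it, but not beside all.

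**Figure D1:**
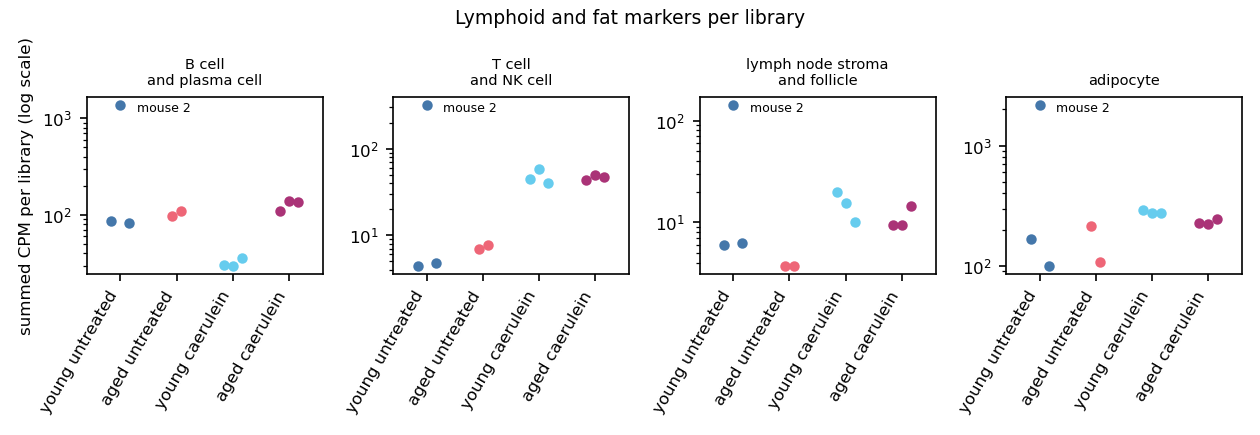
Summed level (CPM of library totals, not TMM scaled, log axis) of 4 marker lists in each of the 11 libraries, by group, 1 point per library. Young untreated mouse 2 stands apart in all 4 panels, by 5.38 to 9.72 times the next highest library.

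In young mice, caerulein was compared with no treatment to see the early injury response. The pancreas had more of the keratin Krt8, the stress factor Atf3 and the inducible heat shock protein Hspa1a, and less of the receptor for caerulein itself. By list, 28 of 35 immediate early and AP-1 genes, 21 of 23 heat shock and oxidative stress genes and 28 of 34 ribosome biogenesis genes rose, and 24 of 34 digestive enzymes and zymogen granule proteins fell. None of these 4 lists passed with an estimated correlation (adjusted p = 0.541, 0.406, 0.54 and 0.82). All 4 passed by fry, which does not compare a list with other genes (adjusted p = 6.65e-06, 1.6e-06, 6.13e-06 and 0.0109). Krt8, a keratin of injured acinar cells, went from 89.5 ± 30.7 to 5710 ± 261 CPM (log2 fold change 6.00 ± 0.28, adjusted p = 4.82e-08), and Atf3, a stress-induced transcription factor, from 1.25 ± 0.164 to 255 ± 13.1 CPM (7.67 ± 0.20). Cckar, the cholecystokinin receptor that caerulein binds, fell from 300 ± 136 to 19.8 ± 3.08 CPM (-3.92 ± 0.35). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 3888 genes were higher and 3488 lower of 14113 tested, and 4181 and 3637 without young untreated mouse 2, with 6593 of the 7376 called again in the same direction. Scaled by library totals alone the median of all genes moved by 0.497 (log2) and the counts became 5314 higher and 1269 lower. Changes here are relative to the TMM-scaled median.

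The largest increases under the naming rule were Kel (the metalloendopeptidase of the Kell blood group, chromosome 6, 41686330 to 41704339, ENSMUSG00000029866), from 0.141 ± 0.127 to 169 ± 4.64 CPM (log2 fold change 10.24 ± 0.39), the inducible heat shock proteins Hspa1a (9.61 ± 0.56) and Hspa1b (9.40 ± 0.52), the tight junction protein Cldn4 (8.58 ± 0.48), Ptx3 and Nfil3. Ptx3, a soluble pattern recognition protein, had few untreated reads, giving a ratio of 274 (95% counting interval 75.6 to 2270). Nfil3, a repressor in the circadian clock, rose by 7.69 ± 0.37 and Dbp, a clock-driven activator, was the second largest decrease at -6.30 ± 0.24 (108 ± 26.9 to 1.37 ± 0.0917 CPM). Also lower were Sostdc1, an antagonist of BMP and Wnt signals (-5.57 ± 0.41), the secretory vesicle GTPase Rab3a (-5.17 ± 0.79) and Smim24 (-5.16 ± 0.47). The fat droplet protein Plin1, with no reads after caerulein (at least 302-fold lower), and Ciita, the master regulator of MHC class II genes (-6.01 ± 1.47), owed much of their untreated level to young untreated mouse 2. Without it the log2 fold change of Ciita was -2.44 ± 0.76. Plin1 lost its call in 2 of the 20 alternatives in which it was tested.

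Among the lists, immediate early and AP-1 genes had the smallest p. Of 35 tested, 28 rose, 0 fell and 7 did not pass (29 rose adjusted over the list alone; camera adjusted p = 8.93e-12, adjusted p = 0.541 with an estimated correlation). Without young untreated mouse 2, 34 rose and 0 fell. Srf (3.74 ± 0.16), Fosl1 (6.41 ± 0.28) and Klf6 (4.97 ± 0.24) had the smallest p with Atf3. Ribosome biogenesis rose in 28 of 34 genes, with none lower and 6 not passed (29 adjusted over the list alone; adjusted p = 1.23e-09, adjusted p = 0.54 with an estimated correlation). The nucleolar proteins Nop58 (2.54 ± 0.14) and Rrp12 (2.44 ± 0.15) were among them. Of 23 heat shock and oxidative stress genes 21 rose and 2 fell, and the counts were equal adjusted over the list alone (adjusted p = 1.88e-09, adjusted p = 0.406 with an estimated correlation). The cytosolic chaperone Hsp90aa1 rose by 4.68 ± 0.27. Srxn1, which repairs oxidised peroxiredoxins, rose by 4.68 ± 0.20. The integrated stress response list had 26 of 30 higher, 2 lower and 2 not passed, also adjusted over the list alone 26 and 2 (adjusted p = 1.65e-07, adjusted p = 0.82 with an estimated correlation). Ppp1r15a, which reverses the translation block of that response, rose from 10.4 ± 1.64 to 78 ± 10.7 CPM and the cystine carrier Slc7a11 by 2.56 ± 0.15. Ddit3, the death-linked factor CHOP, did not pass (0.54 ± 0.45, adjusted p = 0.331; 1.16 and 0.0332 with library totals, 1.20 and 0.0321 without young untreated mouse 1). Metaplasia and injury genes of acinar cells had 23 of 32 higher, 2 lower and 7 not passed (24 and 2 adjusted over the list alone; adjusted p = 1.68e-06, adjusted p = 0.309 with an estimated correlation). Besides Krt8 they included the keratin Krt20 (6.93 ± 0.38) and the growth factor receptor Egfr (4.29 ± 0.18).

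Digestive enzymes and zymogen granule proteins fell in 24 of 34 genes, with none higher and 10 not passed (24 adjusted over the list alone, 29 without young untreated mouse 2; adjusted p = 3.32e-05, adjusted p = 0.82 with an estimated correlation). Colipase (Clps) fell by 1.97 ± 0.20 on the log2 scale and the ribonuclease Rnase1 by 2.12 ± 0.24. Chymotrypsin C (Ctrc) was at -1.79 ± 0.21 and carboxypeptidase A1 (Cpa1) at -1.09 ± 0.21. Cpa1 was at -0.53 with library totals, still called, and lost its call with no filter on low counts (-1.06, adjusted p = 0.0506). The acinar identity list did not pass (6 of 25 higher, 13 lower, 6 not passed; 7 and 13 adjusted over the list alone; adjusted p = 0.119). Its median of -0.50 became 0.07 with library totals. In it Rbpjl, a partner in the acinar factor PTF1, was at -2.91 ± 0.20 and Creb3l1 at -2.16 ± 0.19. The secretory factor Bhlha15 was at -1.78 ± 0.26, while Ptf1a itself rose from 13.2 ± 5.68 to 37.3 ± 2.85 CPM (adjusted p = 0.0015). Endoplasmic reticulum chaperones fell in 19 of 27 genes, with 3 higher and 5 not passed (20 lower and 3 higher adjusted over the list alone; adjusted p = 0.0016, adjusted p = 0.842 with an estimated correlation). Their median of -0.67 became -0.12 with library totals. Pdia4 (-2.09 ± 0.17) and Sdf2l1 (-2.08 ± 0.19) were lower, and the central chaperone Hspa5 was among the 3 that rose (371 ± 96.3 to 1170 ± 120 CPM, 1.65 ± 0.19). Nuclear oxidative phosphorylation genes fell in 16 of 34, with 1 higher and 17 not passed, the same counts adjusted over the list alone (adjusted p = 0.00172, adjusted p = 0.842 with an estimated correlation), but their median of -0.35 became 0.18 with library totals. Without young untreated mouse 2, 27 fell and 1 was higher. The complex IV subunit Ndufa4 was at -0.90 ± 0.10.

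Cytokines and chemokines rose in 14 of 25 tested genes, with 2 lower and 9 not passed (16 and 3 adjusted over the list alone; adjusted p = 0.00175, adjusted p = 0.82 with an estimated correlation). With young untreated mouse 2 left out, 20 of 23 rose and 1 fell. The EGF receptor ligand Hbegf went from 0.848 ± 0.213 to 34.7 ± 7.06 CPM (log2 fold change 5.37 ± 0.22). Lif, of the IL-6 family, rose from 0.237 ± 0.319 to 32.1 ± 2.02 CPM (6.83 ± 0.45). The monocyte chemokine Ccl2 went from 0.0799 ± 0.138 to 9.84 ± 5.74 CPM (adjusted p = 5.62e-05). Il6 (ratio 34.8, 95% counting interval 5.89 to 1410) and the neutrophil chemokine Cxcl2 (ratio 140, 24.8 to 5560) passed at 0.537 ± 0.464 and 2.19 ± 1.75 CPM in treated mice. Il1b (adjusted p = 0.021) lost its call without young untreated mouse 1 (adjusted p = 0.0559) and Cxcl1 (adjusted p = 0.0173) without young caerulein mouse 2 (adjusted p = 0.0994). Tnf did not pass (0.72, adjusted p = 0.636), but it did as higher without young untreated mouse 2 (3.96, adjusted p = 0.029) and with the lymphoid covariate (4.08, 0.0261), and by DESeq2 without that mouse (4.21). STAT3 and acute phase genes rose in 11 of 23, with 12 not passed and equal counts adjusted over the list alone (adjusted p = 0.00397, adjusted p = 0.82 with an estimated correlation). Leaving out young untreated mouse 2, 16 of 22 rose and 1 fell. Lcn2, an iron-withholding acute phase protein, rose by 6.45 ± 0.35 and Stat3 by 1.27 ± 0.14. NF-kB targets had 5 of 27 higher, 2 lower and 20 not passed (5 and 1 adjusted over the list alone; adjusted p = 0.644), where the median (-0.17) and mean (-0.06) were negative and the test direction was up. With young untreated mouse 2 left out, 15 NF-kB targets were higher and 1 lower (adjusted p = 0.00564).

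Cell cycle genes in young mice fell in 14 of 23, with 1 higher and 8 not passed (16 and 1 adjusted over the list alone; adjusted p = 0.000397, adjusted p = 0.82 with an estimated correlation), and in 9 of 19 without young untreated mouse 2. The replication licensing factor Mcm2 was at -1.81 ± 0.23. Apoptosis and p53 targets rose in 10 of 22, with 3 lower and 9 not passed, equal adjusted over the list alone (adjusted p = 0.00984, adjusted p = 0.586 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 7.24 ± 0.24 and the antiproliferative Btg2 by 4.54 ± 0.26. Cytosolic ribosomal proteins rose in 20 of 36, with 16 not passed and equal counts adjusted over the list alone (adjusted p = 0.00175, adjusted p = 0.842 with an estimated correlation). Red blood cell genes fell in 5 of 6, also adjusted over the list alone (adjusted p = 0.0223, adjusted p = 0.82 with an estimated correlation). Interferon-stimulated genes fell in 13 of 32, with 1 higher (12 and 0 adjusted over the list alone; adjusted p = 0.0246, adjusted p = 0.876 with an estimated correlation). Of these, 4 rose and 4 fell without young untreated mouse 2 (adjusted p = 0.302), and the list also missed the threshold without young caerulein mouse 1 (adjusted p = 0.063). MHC class II genes, whose list did not pass (adjusted p = 0.197), fell in 8 of 10 with that library and in 1 without it. All 12 tested B cell and plasma cell markers fell with it (list adjusted p = 0.0571) and 1 of 8 without it.

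In aged mice the same treatment gave a response of like size, with Krt8, Atf3 and Lif higher and Cckar lower. Krt8 went from 98.9 ± 3.03 to 6660 ± 233 CPM (log2 fold change 6.07 ± 0.34, adjusted p = 2.63e-07) and Atf3 from 1.48 ± 0.171 to 360 ± 59 CPM (7.94 ± 0.24). Cckar fell from 365 ± 24.2 to 18.6 ± 4.12 CPM (-4.29 ± 0.37). Lif had no reads in either aged untreated library and 103 ± 7.65 CPM after caerulein, at least 1030-fold higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3806 genes were higher and 2998 lower. Without young untreated mouse 2, which is in neither group but enters the filter (13567 genes tested without it), scaling and spread, they were 4164 and 3748 (6728 of 6804 called again in the same direction). Without aged untreated mouse 2 the lower count was 1977 and without mouse 3 it was 1970, each leaving 1 untreated library whose spread was taken from the other groups. Library totals alone moved the median of all genes by 0.615 (log2) and gave 5451 higher and 1074 lower.

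Under the naming rule the largest increases after Lif were Tac1, which encodes substance P (no untreated reads, at least 256-fold), and Peg10 (no untreated reads, at least 71.3-fold). Ratios with 95% counting intervals were 3080 (553 to 122000) for Hspa1a, 2110 (583 to 17400) for the ERK phosphatase Dusp5 and 1940 (665 to 9420) for Kel. The largest decreases were Fam81a (-6.68 ± 0.64), Dbp (-6.45 ± 0.25), Nxph2 (-5.49 ± 0.93) and Sostdc1 (-5.32 ± 0.41). Next came the fatty acid desaturase Scd2 (132 ± 23.3 to 4.54 ± 1.41 CPM, -4.87 ± 0.35) and the mitochondrial phosphatase Pdp2 (-4.76 ± 0.41). Immediate early and AP-1 genes rose in 32 of 35, with 3 not passed (33 adjusted over the list alone; camera adjusted p = 2.04e-14, adjusted p = 0.412 with an estimated correlation). Fosl1 (7.89 ± 0.38), Srf (4.23 ± 0.20) and Klf10 (4.12 ± 0.20) were among them. Ribosome biogenesis rose in 29 of 34, with 5 not passed (31 adjusted over the list alone; adjusted p = 7.11e-10, adjusted p = 0.412 with an estimated correlation; Nop58 3.00 ± 0.17). Heat shock and oxidative stress genes rose in 20 of 23, with 1 lower and 2 not passed, equal adjusted over the list alone (adjusted p = 2.12e-08, adjusted p = 0.412 with an estimated correlation). Hspa8 was at 3.83 ± 0.28 and Srxn1 at 5.71 ± 0.25. The integrated stress response list had 25 of 30 higher, 1 lower and 4 not passed, equal adjusted over the list alone (adjusted p = 6.12e-07, adjusted p = 0.712 with an estimated correlation). Ppp1r15a was at 3.41 ± 0.19, the mTOR inhibitor Ddit4 at 3.59 ± 0.31 and Ddit3 not passed (0.60 ± 0.52, adjusted p = 0.371).

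Metaplasia and injury genes rose in 21 of 32 in aged mice, with 1 lower and 10 not passed, equal adjusted over the list alone (adjusted p = 1.83e-06, adjusted p = 0.334 with an estimated correlation). Klf5, an epithelial growth regulator, was at 4.30 ± 0.27. The ductal factor Sox9 rose from 11.5 ± 0.991 to 31.9 ± 2.64 CPM (1.46 ± 0.30). In young mice it did not pass (0.13 ± 0.26, adjusted p = 0.709) except with library totals (0.68, adjusted p = 0.0357), and the difference between the responses did not pass either (1.34 ± 0.39, adjusted p = 0.211). The ductal keratin Krt19 rose at both ages (10.8 ± 6.19 to 130 ± 6.53 CPM in young, 8.62 ± 1.24 to 98.4 ± 19.2 CPM in aged). Ductal markers as a list did not pass camera at either age. Of 20 genes, 6 rose, 3 fell and 11 did not pass in young mice (adjusted p = 0.428). In aged mice 6 rose, 4 fell and 10 did not pass (adjusted p = 0.876), and at both ages the counts were equal adjusted over the list alone. Digestive enzymes fell in 23 of 34, with 1 higher and 10 not passed, equal adjusted over the list alone (adjusted p = 1.83e-06, adjusted p = 0.712 with an estimated correlation). Clps was at -2.13 ± 0.22, Rnase1 at -2.49 ± 0.26 and Ctrc at -2.15 ± 0.22. The acinar identity list did not pass (5 of 25 higher, 13 lower, 7 not passed; 6 and 14 adjusted over the list alone; adjusted p = 0.0581), and its median of -0.62 became -0.00233 with library totals. In it Rbpjl was at -2.73 ± 0.21 and Ptf1a at -0.04 ± 0.34 (adjusted p = 0.934), which became 0.56 with library totals. The difference between the Ptf1a responses did not pass (-1.54 ± 0.45, adjusted p = 0.204). Nuclear oxidative phosphorylation genes fell in 27 of 34, with 7 not passed (29 adjusted over the list alone; adjusted p = 1.44e-07, adjusted p = 0.712 with an estimated correlation). Their median of -0.69 became -0.08 with library totals. The succinate dehydrogenase subunit Sdhb was at -1.27 ± 0.15. Endoplasmic reticulum chaperones were mixed (5 of 27 higher, 11 lower and 11 not passed; 5 and 12 adjusted over the list alone; adjusted p = 0.284), with a median of -0.26 that became 0.36 under library totals. Hspa5 went from 331 ± 25 to 1850 ± 77.3 CPM (2.48 ± 0.23) and Sel1l, of the degradation machinery, fell (-2.54 ± 0.24).

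Cytokines and chemokines rose in 13 of 25 in aged mice, with 1 lower and 11 not passed (14 and 1 adjusted over the list alone; adjusted p = 0.00134, adjusted p = 0.738 with an estimated correlation). Hbegf went from 0.646 ± 0.082 to 117 ± 11.2 CPM (log2 fold change 7.46 ± 0.28). The macrophage chemokine Ccl9 went from 0.893 ± 0.193 to 18.9 ± 4.13 CPM (4.36 ± 0.52), and Ccl2 from no reads to 5.62 ± 1.2 CPM, at least 55.5-fold. Cxcl2 (at least 6.25-fold, adjusted p = 0.0261) and Cxcl1 (at least 7.82-fold, adjusted p = 0.0471) passed. Cxcl2 lost its call without aged untreated mouse 2 (0.0927) or 3 (0.132) or aged caerulein mouse 1 (0.0638). Cxcl1 lost it without aged untreated mouse 2 (0.145) or 3 (0.191), young caerulein mouse 1 (0.0533), or aged caerulein mouse 1 (0.0694), 2 (0.1) or 3 (0.0506). Il6 (adjusted p = 0.0679; 0.0452 with library totals and 0.0427 without young caerulein mouse 3), Tnf (adjusted p = 0.238) and Il1b (adjusted p = 0.233) did not pass, with levels of 0.218 ± 0.13, 0.146 ± 0.206 and 0.12 ± 0.0288 CPM after caerulein. STAT3 and acute phase genes rose in 14 of 23, with 9 not passed (15 adjusted over the list alone; adjusted p = 0.000174, adjusted p = 0.712 with an estimated correlation). Lcn2 was at 5.92 ± 0.42 and Stat3 at 2.01 ± 0.16. Apoptosis and p53 targets rose in 11 of 22, with 2 lower and 9 not passed (11 and 3 adjusted over the list alone; adjusted p = 0.00578, adjusted p = 0.555 with an estimated correlation). Cdkn1a was at 7.03 ± 0.28. Cell cycle genes fell in 8 of 23, with 1 higher and 14 not passed (7 and 1 adjusted over the list alone; adjusted p = 0.0144, adjusted p = 0.76 with an estimated correlation). Mcm2 was at -2.62 ± 0.25. Mitochondrially encoded genes fell in 10 of 14, with 2 higher and 2 not passed, equal adjusted over the list alone (adjusted p = 0.0176, adjusted p = 0.817 with an estimated correlation). Their median of -0.86 became -0.26 with library totals. In young mice they fell in 10 of 14, with 2 higher (11 and 2 adjusted over the list alone; adjusted p = 0.044, adjusted p = 0.842 with an estimated correlation). There the median of -0.70 became -0.18 with library totals. The young mitochondrial call was lost without young untreated mouse 1 (adjusted p = 0.0749) or 3 (0.0826), aged untreated mouse 3 (0.0504), young caerulein mouse 1 (0.0975) or 2 (0.0728), or aged caerulein mouse 2 (0.0505).

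Set side by side across 14113 genes, the log2 fold changes of the 2 responses had a Pearson correlation of 0.738 and a Spearman correlation of 0.785, described only, since genes are not independent replicates. Without young untreated mouse 2 the Pearson value was 0.874, without aged untreated mouse 2 it was 0.548 and without aged untreated mouse 3 it was 0.495. The called genes overlapped far beyond independence, with 3188 higher at both ages (1049 if independent) and 2309 lower at both (741 if independent). In all, 5497 genes were called in the same direction at both ages, 9 in opposite directions, 1870 in young alone and 1298 in aged alone. A call at 1 age alone is not evidence of a difference, which is tested separately.

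**Figure D2:**
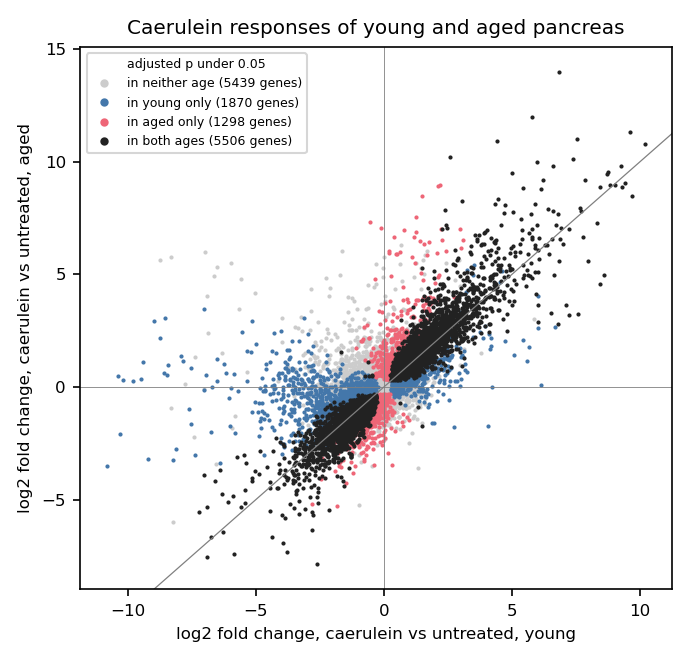
Log2 fold change after caerulein of each of 14113 genes in young mice (x axis) and aged mice (y axis), coloured by whether the gene was called at both ages (5506, of them 9 in opposite directions), in young alone (1870), in aged alone (1298) or at neither (5439). Points follow the diagonal, with a correlation across genes of 0.738.

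Untreated aged mice were compared with untreated young mice to find differences of age before injury. Few genes were called, among them Cobl, an actin nucleator, and 3 secreted Reg proteins. Cobl (chromosome 11, 12236608 to 12464960, ENSMUSG00000020173) was at 2.73 ± 0.399 CPM in young and 41 ± 7.22 CPM in aged mice (log2 fold change 3.92 ± 0.17, adjusted p = 9.01e-07). Reg2 was at 6050 ± 2520 CPM in young and 102 ± 70.3 CPM in aged mice (-5.89 ± 0.83). Reg3b (chromosome 6, 78370657 to 78373466, ENSMUSG00000071356) was at 1310 ± 755 and 24.3 ± 12.1 CPM (-5.76 ± 0.76) and Reg3a at 267 ± 141 and 3.71 ± 1.41 CPM (-6.20 ± 0.84). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 genes were higher and 5 lower in aged mice, and 1320 had an unadjusted p below 0.05. Leaving out young untreated mouse 2 gave 35 higher and 20 lower, all 13 among them in the same direction. Library totals alone moved the median of all genes by -0.233 (log2) and left 3 higher and 0 lower by edgeR.

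Also higher in aged untreated mice were the osteocalcin-related Bglap3 (3.19 ± 0.36), Bdh2 (2.66 ± 0.36), Nexmif (2.49 ± 0.30), the protease inhibitor Serpine2 (2.07 ± 0.27) and the retinol dehydrogenase Rdh11 (1.36 ± 0.17). Ucp2, a carrier of the inner mitochondrial membrane (-2.34 ± 0.36), and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation (-0.85 ± 0.13), were lower. The other called genes, 1810007D17Rik and Fxyd1, fall outside the naming rule and were chosen for mention after their values were seen. Cobl kept its call with each library left out. Of the 11 genes named here, the other 10 lost it without aged untreated mouse 2 (adjusted p = 0.11 to 0.673) and without mouse 3 (adjusted p = 0.236 to 0.82). EdgeR then called 2 genes higher and 0 lower. Ucp2 lost its call without any library but young untreated mice 1 and 2 (adjusted p = 0.0565 to 0.82), and Cpt1a without any but young untreated mouse 2 (adjusted p = 0.0614 to 0.82). Without young untreated mouse 3, Bdh2 (adjusted p = 0.0614) and Reg2 (0.0566) were lost. Without aged caerulein mouse 1, Bdh2 (0.0533), Reg3a (0.0563) and Reg2 (0.0637) were lost, and without young caerulein mouse 1 or 2, Reg2 (0.0549 and 0.0635). The count of lower genes was 2 without young untreated mouse 3 or young caerulein mouse 1 or 2, 1 without aged caerulein mouse 1, and 3 without young caerulein mouse 3 or aged caerulein mouse 2.

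Of 40 lists, 23 passed camera in untreated mice (9 higher and 14 lower in aged), and 11 did without young untreated mouse 2. Some of the 11 passed only without it. B cell and plasma cell markers were then higher in aged mice (3 of 8 called, adjusted p = 2.56e-06). So were MHC class II genes (2 of 10, 5.69e-06) and macrophage and monocyte markers (0 of 25, 0.000214). Islet cell markers (0 of 29, 0.000247) and endoplasmic reticulum chaperones (0 of 27, 0.0177) were then lower. With an estimated correlation their adjusted p was 0.115, 0.202, 0.591, 0.799 and 0.715. The 17 of the 23 that missed the threshold without it included NF-kB targets, immediate early genes, interferon-stimulated genes, lymph node markers, adipocyte markers and digestive enzymes. The other 6 passed with and without it, and each passed with any other library left out except where named. Cytosolic ribosomal proteins were higher as a list in aged mice although 0 of 36 passed singly or adjusted over the list alone (median 0.30; adjusted p = 8.56e-14, adjusted p = 0.671 with an estimated correlation; Rpl5 0.60 ± 0.15, adjusted p = 0.345). The Reg family and pancreatic stress proteins were lower, with 3 of 10 called and 5 adjusted over the list alone (adjusted p = 8.28e-06, adjusted p = 0.263 with an estimated correlation; Reg3d, at 430 ± 84.7 and 212 ± 52.6 CPM, did not pass). Collagens and matrix genes were lower as a list with 0 of 30 called and 2 adjusted over the list alone (adjusted p = 5.77e-06, adjusted p = 0.671 with an estimated correlation; Col4a1 -0.65 ± 0.16, adjusted p = 0.317). Red blood cell genes were lower with 0 of 6 called and 5 adjusted over the list alone (adjusted p = 7.78e-05, adjusted p = 0.671 with an estimated correlation). Mitochondrially encoded genes were higher with 0 of 14 called, also adjusted over the list alone (adjusted p = 8.05e-05, adjusted p = 0.671 with an estimated correlation). Cholesterol synthesis genes were higher with 0 of 22 called and 1 adjusted over the list alone (adjusted p = 0.00137, adjusted p = 0.671 with an estimated correlation; 0.15 without aged untreated mouse 3), as in Insig1, a sterol sensor (0.80 ± 0.17, adjusted p = 0.188). Leaving out young untreated mouse 2, Reg3d (adjusted p = 0.00519) and Insig1 (0.0425) passed, and by DESeq2 on all libraries Reg3d, Insig1, Rpl5 (0.019) and Col4a1 (0.0346) did. In the simulation of this comparison DESeq2 called 23 unchanged genes and edgeR 4.

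Aged and young mice given caerulein were compared to find how the injured tissue differed with age. Aged tissue had more of the metabolic stress hormone Fgf21, the glucose transporter Slc2a1, the growth factors Hbegf and Lif, the ductal factor Sox9 and 9 of 27 endoplasmic reticulum chaperones, and less of the injury markers Krt20 and Cldn4. The metaplasia and injury list that holds these 2 markers did not pass (camera adjusted p = 0.924, median 0.02). In it 2 of 32 genes were higher, 3 lower and 27 not passed, equal adjusted over the list alone. The ductal list that holds Sox9 did not pass either (camera adjusted p = 0.93, median 0.09). Of its 20 genes 1 was higher, 1 lower and 18 not passed (1 and 2 adjusted over the list alone). As a list the chaperones did not pass with an estimated correlation (adjusted p = 0.964) or by fry (adjusted p = 0.129), and Hspa5 did not pass. Fgf21 (chromosome 7, 45613886 to 45615490, ENSMUSG00000030827) was at 10.1 ± 1.2 CPM in young and 82.7 ± 32.4 CPM in aged mice (log2 fold change 3.03 ± 0.41, adjusted p = 0.00308). In untreated mice it was at 16.5 ± 8.69 and 55.5 ± 4.43 CPM. Slc2a1 was at 5.86 ± 1.64 and 42.1 ± 5.67 CPM (2.84 ± 0.24), and Sox9 at 8.35 ± 3.15 and 31.9 ± 2.64 CPM (1.93 ± 0.26). Krt20 (chromosome 11, 99428403 to 99438150, ENSMUSG00000035775) was at 45.5 ± 10.9 CPM in young and 5.22 ± 1.43 CPM in aged mice (-3.12 ± 0.28, adjusted p = 0.000438), and Cldn4 at 343 ± 111 and 44.4 ± 15.4 CPM (-2.95 ± 0.35).

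By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 347 genes were higher and 179 lower in aged caerulein mice. Without young untreated mouse 2, which is in neither group, 1065 were higher and 856 lower, all 526 called again in the same direction. Without young caerulein mouse 1, 2 or 3 the higher counts were 147, 184 and 109 and the lower counts 68, 85 and 62. Without aged caerulein mouse 1, 2 or 3 they were 173, 151 and 169 higher and 75, 60 and 69 lower, and without aged untreated mouse 2 or 3 the lower counts were 102 and 103. Library totals alone moved the median by -0.116 (log2) and gave 99 higher and 116 lower. Of 33 called genes that the naming rule gave, 19 kept their call with each library left out and under every other setting.

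Other large increases in aged caerulein mice were Cobl (16.6 ± 1.95 and 122 ± 6.43 CPM, 2.88 ± 0.15), Bglap3 (2.87 ± 0.30), the kinase Aatk (2.71 ± 0.28) and Tac1 (4 ± 0.146 and 24.7 ± 4.12 CPM, 2.63 ± 0.24). Lower were the glucuronosyltransferase Ugt2b34 (-3.55 ± 0.55), the kallikrein Klk1b24 (-2.85 ± 0.42), the kinase Sgk2 (-2.66 ± 0.30) and Reg2 (-2.44 ± 0.59, adjusted p = 0.0462). The Reg2 call was lost without aged untreated mouse 2 (adjusted p = 0.0615) or 3 (0.0612), young caerulein mouse 1 (0.147) or 2 (0.119), or aged caerulein mouse 1 (0.128), 2 (0.162) or 3 (0.102). Ptf1a, the acinar lineage factor, was at 37.3 ± 2.85 CPM in young and 12.1 ± 3.38 CPM in aged mice (-1.63 ± 0.30, adjusted p = 0.0134), lost without young caerulein mouse 1 (0.0584) or 3 (0.0515) or aged caerulein mouse 1 (0.0667) or 3 (0.0669). The acinar identity list that holds Ptf1a did not pass (camera adjusted p = 0.249, median 0.16). Of its 25 genes 2 were higher, 1 (Ptf1a) was lower and 22 did not pass (3 and 1 adjusted over the list alone). Hbegf was at 34.7 ± 7.06 and 117 ± 11.2 CPM (1.75 ± 0.16, adjusted p = 0.000582). Lif was at 32.1 ± 2.02 and 103 ± 7.65 CPM (1.68 ± 0.29, adjusted p = 0.013), lost without young caerulein mouse 1 (0.0668), 2 (0.0594) or 3 (0.083) or aged caerulein mouse 2 (0.0616). Gclc, the rate-limiting enzyme of glutathione synthesis, was at 72.7 ± 14 and 362 ± 134 CPM (2.32 ± 0.29) and Serpinh1, a collagen chaperone, at 83.5 ± 14.5 and 29.9 ± 5.92 CPM (-1.48 ± 0.19). The heat shock and oxidative stress list that holds Gclc did not pass (camera adjusted p = 0.173). In it 2 of 23 genes were higher, 6 lower and 15 not passed (3 and 9 adjusted over the list alone).

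Endoplasmic reticulum chaperones were higher in aged caerulein mice in 9 of 27 genes, with 18 not passed (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.38e-07, adjusted p = 0.964 with an estimated correlation), and in 16 without young untreated mouse 2. Hyou1 was at 48.3 ± 5.93 and 113 ± 11.3 CPM (1.23 ± 0.17) and Hsp90b1 at 69.3 ± 6.41 and 132 ± 17.1 CPM (0.93 ± 0.13). Sdf2l1 was at 10.9 ± 0.867 and 27.6 ± 4.23 CPM (1.34 ± 0.19), while Hspa5 did not pass (0.66 ± 0.19, adjusted p = 0.0795). Immediate early and AP-1 genes were higher in 7 of 35, with 28 not passed (14 adjusted over the list alone; adjusted p = 1.77e-05, adjusted p = 0.964 with an estimated correlation). Without young untreated mouse 2, 17 were higher and 1 lower. Klf4, a zinc finger factor of that list, was at 17.3 ± 1.89 and 35.8 ± 5.18 CPM (1.05 ± 0.14), while Fos (1.26 ± 0.40, adjusted p = 0.118) and Egr1 (1.42 ± 0.43, adjusted p = 0.0982) did not pass. Leaving out young untreated mouse 2, Hspa5 (adjusted p = 0.00102), Fos (0.00728) and Egr1 (0.00561) passed. Ribosome biogenesis was higher with 1 of 34 called and 6 adjusted over the list alone (adjusted p = 4.05e-05, adjusted p = 0.964 with an estimated correlation). With young untreated mouse 2 left out, 8 were higher and 1 lower. The integrated stress response was higher with 2 of 30 called and 3 adjusted over the list alone (adjusted p = 0.00713, 0.0702 without young caerulein mouse 1; adjusted p = 0.964 with an estimated correlation). The arginine transporter Slc7a1 was 1 of them (1.23 ± 0.17). Of the same 30 genes, 10 were higher without young untreated mouse 2. Nuclear oxidative phosphorylation genes were lower as a list with 0 of 34 called, also adjusted over the list alone (adjusted p = 0.00713, 0.0534 without young caerulein mouse 3; adjusted p = 0.964 with an estimated correlation). Collagens and matrix genes were lower with 1 of 30 called and 3 adjusted over the list alone (adjusted p = 0.0077, 0.0658 without aged caerulein mouse 1; adjusted p = 0.964 with an estimated correlation).

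The inflammatory genes fixed for naming did not pass between ages after caerulein. Values in young and aged mice were 0.537 ± 0.464 and 0.218 ± 0.13 CPM for Il6 (adjusted p = 0.467), 0.552 ± 0.264 and 0.146 ± 0.206 CPM for Tnf (0.521) and 1.99 ± 2.35 and 0.12 ± 0.0288 CPM for Il1b (0.089). They were 2.51 ± 2.82 and 0.766 ± 0.502 CPM for Cxcl1 (0.419), 2.19 ± 1.75 and 0.561 ± 0.473 CPM for Cxcl2 (0.256) and 9.84 ± 5.74 and 5.62 ± 1.2 CPM for Ccl2 (0.446). Il33, an alarmin, was at 1.24 ± 0.554 and 5.11 ± 3.09 CPM (0.122). Without young untreated mouse 2, Il1b (adjusted p = 0.0155), S100a8 (0.0152) and S100a9 (0.0199) passed as lower and Il33 (0.00889) as higher in aged mice. The cytokine list did not pass (2 of 25 higher, 23 not passed; 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.778). Neither did NF-kB targets (0 of 27 called, also adjusted over the list alone; adjusted p = 0.778). Neutrophil markers were lower as a list in aged mice with 0 of 14 called, also adjusted over the list alone (adjusted p = 0.0169, adjusted p = 0.964 with an estimated correlation), lost without young caerulein mouse 1 (0.0543) or 2 (0.27). With young untreated mouse 2 left out, 4 of 14 were lower (adjusted p = 0.0133, adjusted p = 0.621 with an estimated correlation). S100a8 was at 2.13 ± 2.35 and 0.124 ± 0.124 CPM, not passed (0.149). B cell and plasma cell markers were higher with 1 of 12 called, also adjusted over the list alone (adjusted p = 0.0138, adjusted p = 0.964 with an estimated correlation), lost without aged untreated mouse 2 (0.107) or 3 (0.114). That 1 gene was Derl3, which the chaperone list also holds. Its call was lost without each of the caerulein libraries in turn (adjusted p = 0.0515 to 0.0966). Without young untreated mouse 2, 5 of 8 markers, Derl3 among them, were higher (list adjusted p = 2.5e-06, adjusted p = 0.215 with an estimated correlation). In that list the antibody light chain Igkc was at 0.11 ± 0.147 and 18.5 ± 3.78 CPM, not passed (adjusted p = 0.172) but passed without young untreated mouse 2 (adjusted p = 1.94e-05), whose spread the test shares.

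The difference between the 2 caerulein responses asks directly whether age changed the response. Atp6v1b2, a subunit of the proton pump that acidifies lysosomes, and Dtx4, a Deltex ubiquitin ligase of the Notch pathway, were the called genes. Atp6v1b2 (chromosome 8, 69088646 to 69113711, ENSMUSG00000006273) went from 19.7 ± 0.483 to 40.1 ± 3.57 CPM in young and from 18.6 ± 0.928 to 124 ± 17.2 CPM in aged mice (log2 difference 1.71 ± 0.19, adjusted p = 0.0159). Dtx4 (chromosome 19, 12466341 to 12501996, ENSMUSG00000039982) went from 10.8 ± 0.143 to 60.1 ± 7.21 CPM in young and from 12.9 ± 2.08 to 21 ± 2.24 CPM in aged mice (-1.76 ± 0.20, adjusted p = 0.0159). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment these were the 1 higher and 1 lower gene, and 1758 genes had an unadjusted p below 0.05. The counts were 201 and 110 without young untreated mouse 2, both genes among them (adjusted p = 0.00168 each). Library totals moved the median by 0.116 (log2) and left 0 calls by edgeR, while DESeq2's Wald test called 179 higher and 100 lower. Both calls were lost without aged untreated mouse 2 (Atp6v1b2 0.125, Dtx4 0.116) or 3 (0.32 and 0.0769), young caerulein mouse 1 (0.0779 each) or 3 (0.0958 each), or aged caerulein mouse 2 (0.0527 each) or 3 (0.0707 each). EdgeR then called 0 genes. The higher count was 2 without young untreated mouse 1 and 3 without aged caerulein mouse 1, and the lower count was 2 without young untreated mouse 3.

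Among the lists, immediate early and AP-1 genes were higher as a list in the aged response, with 0 of 35 called singly and 12 adjusted over the list alone (median 1.24; camera adjusted p = 2.67e-09, adjusted p = 0.676 with an estimated correlation). With young untreated mouse 2 left out the median was 0.69, with 4 called (adjusted p = 1.36e-06). In it Klf4 (log2 difference 1.26 ± 0.23) and Klf10 (1.08 ± 0.23) did not pass singly (adjusted p = 0.0816 and 0.11). Endoplasmic reticulum chaperones were higher as a list in the aged response, with 0 of 27 called and 10 higher and 1 lower adjusted over the list alone (median 0.32; adjusted p = 0.000214, adjusted p = 0.863 with an estimated correlation). With young untreated mouse 2 left out, 13 chaperones were called higher and 1 lower (median 0.51; adjusted p = 1.71e-10). Hyou1 (1.43 ± 0.26), Hsp90b1 (1.08 ± 0.20) and Pdia4 (1.30 ± 0.24) each had an adjusted p of 0.0816. Nuclear oxidative phosphorylation genes were lower as a list in the aged response, with 0 of 34 called, also adjusted over the list alone (median -0.32; adjusted p = 4.61e-07, adjusted p = 0.863 with an estimated correlation; 0.000265 without young untreated mouse 2). By fry none of these 3 lists passed (adjusted p = 0.222 for immediate early and AP-1 genes, 0.422 for endoplasmic reticulum chaperones and 0.314 for nuclear oxidative phosphorylation genes). The Reg family list was higher with 0 of 10 called and 5 adjusted over the list alone (adjusted p = 0.0175, adjusted p = 0.676 with an estimated correlation), lost without young untreated mouse 3 (0.0787) or aged untreated mouse 3 (0.0909). Its median was 0.67, and 0.88 without young untreated mouse 2, where 3 were called higher (adjusted p = 0.0045, adjusted p = 0.662 with an estimated correlation). Reg3b fell in young mice, from 1310 ± 755 to 128 ± 58.5 CPM, and was at 24.3 ± 12.1 and 34.9 ± 16.2 CPM in aged mice (log2 difference 3.88 ± 0.83, adjusted p = 0.11). Single genes with large differences that did not pass included Gclc (2.91 ± 0.45, adjusted p = 0.0598), Hbegf (2.10 ± 0.37, adjusted p = 0.0816) and Cldn4 (-3.61 ± 0.67, adjusted p = 0.0816). Leaving out young untreated mouse 2, Gclc (adjusted p = 0.00536), Hbegf (0.0211) and Cldn4 (0.0291) passed, as did Klf4 (0.0202), Klf10 (0.0263), Hyou1 (0.00168), Hsp90b1 (0.00536), Pdia4 (0.0175) and Reg3b (0.0243). All 9 also passed by DESeq2 on all libraries, and Gclc, Hbegf and Cldn4 had an adjusted p of up to 0.378, 0.388 and 0.625 with other libraries left out. In the simulation of this comparison DESeq2 called 18 unchanged genes and edgeR 3.

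**Figure D3:**
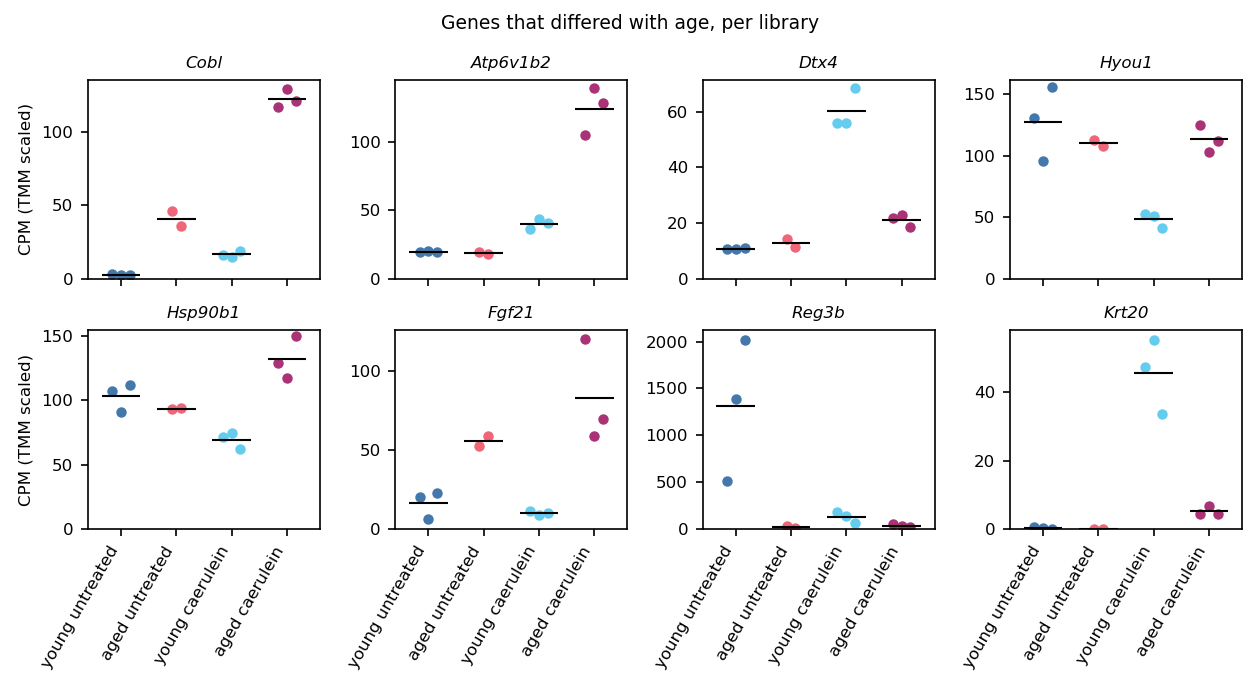
Level (CPM, TMM scaled) of 8 genes in each of the 11 libraries by group, 1 point per library with a line at the group mean. Atp6v1b2 reached 124 CPM after caerulein in aged and 40.1 CPM in young mice, Dtx4 reached 21 and 60.1 CPM, and Krt20 reached 5.22 and 45.5 CPM.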

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

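The tests of tissue, labels, scaling and plasma cells given here were chosen only after the result was seen, while the counts over other splits of the libraries were planned.

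A test of the difference between the young and aged caerulein responses singled out 2 genes and 11 gene lists. Atp6v1b2 rose more in aged mice (log2 difference 1.71) and Dtx4 rose less (-1.76). Higher in the aged response were immediate early and AP-1 genes (camera adjusted p = 2.67e-09), endoplasmic reticulum chaperones (adjusted p = 0.000214), red blood cell genes (adjusted p = 0.000321), interferon-stimulated genes (adjusted p = 0.00062), STAT3 and acute phase genes (adjusted p = 0.00444), B cell and plasma cell markers (adjusted p = 0.0118), the Reg family (adjusted p = 0.0175) and NF-kB targets (adjusted p = 0.0406). Lower were nuclear oxidative phosphorylation genes (adjusted p = 4.61e-07), cytosolic ribosomal proteins (adjusted p = 0.00062) and cholesterol synthesis genes (adjusted p = 0.0115). None of the 11 passed camera with an estimated correlation (adjusted p = 0.676 or 0.863). Red blood cell genes had a median difference of 2.76 over 6 genes, and of 1.26 over 5 genes without young untreated mouse 2. Without young untreated mouse 2, 4 of the 11 missed the threshold, which were interferon-stimulated genes (0.201), STAT3 genes (0.156), B cell and plasma cell markers (0.169) and NF-kB targets (0.597). NF-kB targets also missed it without aged untreated mouse 2 (0.0943), young caerulein mouse 1 (0.111), aged caerulein mouse 2 (0.0847) or 3 (0.0539). Cytosolic ribosomal proteins did so without aged caerulein mouse 3 (0.0529), cholesterol synthesis genes without young untreated mouse 3 (0.0531) or aged untreated mouse 3 (0.156), and the Reg family without the same libraries (0.0787 and 0.0909). The calls of Atp6v1b2 and Dtx4 were lost without aged untreated mouse 2 (0.125 and 0.116) or 3 (0.32 and 0.0769), young caerulein mouse 1 (0.0779 each) or 3 (0.0958 each), or aged caerulein mouse 2 (0.0527 each) or 3 (0.0707 each).

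The first pattern weighed is the lymphoid and fat transcripts of young untreated mouse 2. Lymph node and fat tissue in the dissected piece stays open and cannot be told apart from other sources, since the ratio of the 4 marker lists to the next highest library, at least 5.38, measures the lists on which the pattern was found. The antibody light chain Igkc had 6587 counts there and the fat hormone Adipoq 766, against at most 462 and 30 in any other library. A wrong label is argued against. Between the other young untreated libraries (0) and the aged untreated mean (1) its median position was -0.0825 over 55 genes, against 0.791 and 0.952 for the aged untreated libraries placed without themselves, and towards young caerulein it was 0.18 over 7818 genes, against 0.926 to 1.03. The interquartile ranges over genes (-0.488 to 0.531 and -0.163 to 0.536) missed the first bound of 0.5, and the comparison with the other libraries was added after that. Each library was placed over its own set of genes, 24 and 9 for the aged untreated ones. Young untreated mice 1 and 3 were at 0.231 and -0.105 towards aged. Towards young caerulein they were at 0.0215 and 0.037, so mouse 2 lay further that way than they did. No biological explanation was tested.

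The second pattern is the higher value of the endoplasmic reticulum chaperone list in the aged response, a median log2 difference of 0.321 over 27 genes. Young untreated mouse 2 is argued against as the cause, since the median without it did not fall but was 0.51 (SE over genes 0.14). Such an SE takes the 27 genes as independent, while their estimated correlation was 0.622. It does not measure the spread between mice and is likely too small. Scaling cannot be told apart, since over the median of all genes the list stood at 0.259 under TMM and 0.2 with library totals, with an SE over genes of 0.143 that keeps it open. Plasma cells, which are rich in these chaperones, are argued against as the whole cause. Between young and aged caerulein libraries 0.0547 CPM of immunoglobulin was gained per CPM gained by the list (0.0348 to 0.106 over the 3 aged libraries), where 1 or more was set as needed. The first bound for ruling them out, 0.1, was exceeded in 1 library, and the comparison with 1 was added after that. Age itself remains an open explanation that was not tested apart from these.

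The third pattern is plasma cell transcripts in aged libraries. Tissue like that of young untreated mouse 2, or reads carried over from it, is argued against. The 5 aged libraries together held 0.891 follicular B and T cell counts per 100 plasma cell counts (41 to 4600, upper 95% limit 1.21), against 13.3 in that library (2464 to 18548). The limit covers counting error of the pooled counts and not the spread between mice. Single aged libraries ranged from 0.272 to 2.78, and 21 of the 41 counts came from aged caerulein mouse 1. Age is again open and untested.

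For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In young caerulein against young untreated mice 1 of the 10, the real one, gave as many as its 7376 called genes, and the highest other gave 0. In aged against young caerulein mice 1 of the 10 gave as many as the real 526, and the highest other gave 0. The outlier test needs groups of 4 or more and was not applied.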

How the results depend on the processing

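The settings that join 2 choices (DESeq2 or an estimated correlation, each without young untreated mouse 2) were tests chosen only after the result was seen, and the other settings were planned.

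The caerulein responses kept at least 1074 calls in each direction under every setting run, while the age comparisons and the difference depended on the test, the scaling and single libraries. Of the called genes named, 58 of 65, 51 of 57, 1 of 11, 19 of 33 and 0 of 2 kept their call everywhere in the young response, aged response, age in untreated, age in caerulein and difference, and no called gene reversed. Where a value moved, the cause was not tested unless the setting itself gives it, as with fewer genes or libraries. Values are given as higher and lower genes. The stricter filter, which tests fewer genes, gave 2520 higher in the young response, 281 lower for age in caerulein and 32 and 25 for the difference. With no filter, age in untreated gave 72 and 635, age in caerulein 307 lower and the difference 547 and 127. A 2-fold minimum gave 2377 and 2219 in the young response, 1967 lower in the aged response and 142 and 88 for age in caerulein. Library totals gave 1269 lower in the young and 1074 lower in the aged response, 3 and 0 for age in untreated, 99 and 116 for age in caerulein and 0 and 0 for the difference. DESeq2's Wald test gave 36 and 27, 590 and 323, and 179 and 100 for the 2 age comparisons and the difference, and without young untreated mouse 2 it gave 50 and 36, 1071 and 667, and 338 and 163. With only the 2 groups compared, age in untreated gave 2 and 0 and age in caerulein 939 and 663, while for the difference this setting is the main model and was not run. A replicate block gave 3 and 0 for age in untreated, 111 lower for age in caerulein and 18 lists for the difference. Over all groups the replicate numbers did not pair the libraries, since 6 of 15 same-numbered pairs had a correlation of deviations from the group means over 0.1 (-0.207 to 0.163) and 4 of 11 libraries correlated best with their own number. The 3 pairs of young untreated and young caerulein libraries were each over 0.1 (0.106, 0.149 and 0.114), and there the block gave 3776 higher and 3098 lower. With a lymphoid covariate the 2 age comparisons and the difference gave 36 and 19, 1137 and 762, and 179 and 81.

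Of the lists, 0 passed camera with an estimated correlation in any comparison, and 0 also without young untreated mouse 2. By fry, 19 passed in the aged response, 1 for age in untreated, 0 for age in caerulein and 0 for the difference. Of the lists past the preset camera test, fry kept 15 of 17 in the young and 12 of 12 in the aged response. It kept 1 of 23 for age in untreated, 0 of 9 for age in caerulein and 0 of 11 for the difference. Leaving out each library in turn gave 3409 to 4181 higher and 2697 to 3637 lower in the young response, 2925 to 4164 and 1970 to 3748 in the aged response, 2 to 35 and 0 to 20 for age in untreated, 109 to 1065 and 60 to 856 for age in caerulein, and 0 to 201 and 0 to 110 for the difference. Lists passed ranged over 15 to 20, 12 to 14, 11 to 26, 7 to 13 and 9 to 17 in that order, and the correlation of the responses over 0.495 to 0.874. The highest gene counts were those without young untreated mouse 2, and the lowest in the aged response and age in untreated those without aged untreated mouse 2 or 3, where the lone library left is assumed to vary like the other groups.

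Among the genes named and the lists past the threshold, directions reversed in 2 uncalled genes and 4 lists. Sox9 in the young response (0.13) was -0.12 with the stricter filter, -0.0935 with the lymphoid covariate and -0.17 with DESeq2 without young untreated mouse 2, was called higher with library totals (0.68, adjusted p = 0.0357), and ranged from -0.24 to 0.29 with libraries left out. Ptf1a in the aged response (-0.04) was 0.56 with library totals and 0.0208 with the covariate, and ranged from -0.29 to 0.10. In age in untreated, without young untreated mouse 2, acinar identity genes (adjusted p = 0.976), cytokines (0.976), ductal markers (0.571) and adipocyte markers (0.11) turned. Over all libraries left out these lists ranged from 5.56e-05 to 0.976, 0.00168 to 0.976, 0.00441 to 0.571 and 2.05e-06 to 0.698, and with young untreated mouse 2 out and an estimated correlation the values were 0.989, 0.989, 0.799 and 0.799. Of lists not past the threshold, 5, 2, 9, 2 and 10 also turned without young untreated mouse 2 in the young response, aged response, age in untreated, age in caerulein and difference, and 4 of the 9 then passed. Il6 was at 0.537 CPM or less in every group's mean, and whether depth or the spread between libraries limited such genes was not tested.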

Other observations

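The genes given here were chosen for mention only after the result was seen, except those of the clock list, and the levels of 1810007D17Rik, Ins2 and Gcg are given without a test.

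The predicted gene 1810007D17Rik parted the ages in every library, at 3.22 to 3.77 CPM in young untreated, 102 to 124 CPM in aged untreated, 0.751 to 0.988 CPM in young caerulein and 42.9 to 54.8 CPM in aged caerulein mice. Islet hormones varied widely between libraries, with Ins2 from 87.4 to 1510 CPM and Gcg from 7.23 to 301 CPM. The clock-driven genes Dbp and Tef and the clock gene Per3 fell and Nfil3 rose after caerulein at both ages. Tef was at -3.45 ± 0.19 in young and -4.60 ± 0.21 in aged mice, and Per3 at -4.46 ± 0.32 and -4.49 ± 0.34. As a whole the circadian clock list did not pass camera, which asks for a shift in 1 direction against other genes, at either age. By fry it passed as lower at both ages (adjusted p = 0.0013 in young and 0.000406 in aged mice). In young mice 7 of its 18 genes were higher and 11 lower, also adjusted over the list alone (camera adjusted p = 0.246, adjusted p = 0.82 with an estimated correlation). In aged mice 6 were higher, 10 lower and 2 not passed (6 and 11 adjusted over the list alone; adjusted p = 0.135, adjusted p = 0.712 with an estimated correlation). The hour of day at which tissue was taken is not given in the sources used here.

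The authors' deposited tables of differential expression called 3247 genes higher and 2813 lower in the young response, 3735 and 2907 in the aged response, 22 and 26 for age in untreated mice and 941 and 617 for age in caerulein mice. Genes called in the same direction there and here numbered 5872, 6125, 13 and 502, with 0 called in opposite directions. Correlations of the log2 fold changes across genes, which are not independent replicates, were 0.971, 0.998, 0.981 and 0.998.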
